A study of Mus musculus with 4 samples.

How the data were processed

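The data were 4 single-nucleus RNA sequencing libraries from brains of adult C57BL/6 mice. Supraspinal neurons, the brain neurons whose axons descend to the spinal cord, had been reached with AAV2-Retro, an adeno-associated virus taken up at axon ends, that was delivered to the cervical cord and carried Sox11 or a control, and tissue was taken 2 weeks later, per the labels. Sox11 is a transcription factor of developing neurons. Nuclei were freed from frozen tissue in lysis buffer, sorted by fluorescence (5000 and 7000 nuclei, per the labels' protocols) and processed with the 3′ kit of 10x Genomics, which reads the ends of transcripts and tags each captured molecule with a unique molecular identifier (UMI). There were 2 libraries per group, named here Control 1, Control 2, Sox11 1 and Sox11 2. The labels do not state how many animals each library came from. The Control libraries differed in sex by Xist (811 and 0.054 CPM in corticospinal-like nuclei) and Ddx3y (0 and 30.2), and so came from different animals, while both Sox11-labelled libraries held both transcripts. Every p-value measures only the spread between these libraries, in which animals, sex and preparation cannot be told apart. The other arms that the series' design text describes, with injury, a time course or embryonic cortex, were not analysed here.

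For each library the authors deposited UMI counts per gene and barcode, which were whole numbers and not normalized. Cell Ranger 7.0.1 and the mouse genome mm10 are named in the submitters' processing notes, whereas Cell Ranger 7.1.0 was used for both Control libraries, 7.2.0 for Sox11 1 and 8.0.0 for Sox11 2, per the file headers. The gene tables shared 32285 genes, and beside them held 0 entries for vector sequences in Control 1, 2 in Control 2, and 13 in Sox11 1 and in Sox11 2. Software version and reference therefore followed the groups, and neither can be told apart from the group. Whether reads in introns were counted is not given in the sources used here. Vector entries were kept out of library sizes and tests. Coordinates came from GENCODE M21 on mm10 by gene ID, which held 32235 of the 32285 IDs. Genes with close relatives, such as Tubb2b among the tubulins, were taken with the counts as deposited and are uncertain to that extent.

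The genes summed to 40527479 UMIs in Control 1, 34215523 in Control 2, 45235380 in Sox11 1 and 61679959 in Sox11 2, over 3681, 2352, 2166 and 4383 barcodes. Median UMIs per barcode were 8555, 11896.5, 18620.5 and 10450, so Sox11 1 was the deepest per nucleus. Barcodes with under 1000 detected genes (367, 11, 37 and 321) or over 5% mitochondrial UMIs (0, 2, 6 and 1) were left out. Doublets were scored with scrublet in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 barcodes, 344 in all. The threshold that scrublet set by itself would have marked 1.25%, 1.70%, 26.8% and 1.21% of barcodes, and the high value of Sox11 1 was treated as an alternative.

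The remaining 11502 nuclei were log-normalised and clustered without batch integration on 3000 variable genes chosen within libraries, without Sox11, Malat1, mitochondrial and sex-linked marker genes. Principal components numbered 30 and neighbours 15, and the Leiden method (igraph 0.11.9) ran at resolution 1 with seed 0, which gave 29 clusters. A cluster took the name of a class, written as "like", where at least 3 markers of 1 of 18 fixed marker lists stood at 4 times the median cluster or more, with CPM (counts scaled to a common library total) of 10 or more and 2 added to each CPM, and no other list had as many. A cluster stayed unnamed where another list held more of its 10 most raised genes, and shallow clusters also needed a marker among these. That condition kept clusters 0 and 15, which led with hindbrain markers, and cluster 1 unnamed. This scoring was set after the data were examined. It named 7 clusters corticospinal-like (layer 5 neurons that project out of the forebrain), 7 hindbrain-like by Hox genes and left 7 unnamed. Clusters not named as glia, 11274 nuclei, were called neuron-like. The names were rebuilt from these data and can differ from the study's own.

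UMI counts were summed per library and class, because nuclei are not replicates, and the sums were compared between 2 Sox11-labelled and 2 Control libraries with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05, two-sided). Standard errors were derived from the fold change and the F statistic of that test. Fits covered all neuron-like nuclei, corticospinal-like nuclei and each other neuronal class or unnamed cluster with 20 or more nuclei in every library. The difference of the effect between corticospinal-like and the other neuron-like nuclei was tested in 1 fit of 8 sums with the library as a term. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so none was used for single values. Shares of nuclei have exact Clopper-Pearson 95% intervals, which cover counting error only.

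The marker lists, 17 gene lists, the tests and the alternatives for the processing were set before the data were examined, except where stated. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it, in corticospinal-like, all neuron-like and the other neuron-like nuclei and for the difference of effects. Named genes were Sox11 and the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean CPM of 10 or more and no overlap of CPM between the groups, without predicted gene models, mitochondrial genes or sex-linked marker genes. For other classes the limit was 4 each way, or the 10 lowest p-values where no gene passed, for the difference 6 each way without the overlap condition, and for each list the 4 members of lowest p. Further list members were named after their values were seen.

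Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, each library left out in turn, other limits on detected genes and mitochondrial UMIs, no doublet removal, equal nuclei per library, other cluster resolutions and a marker gate. Alternatives chosen after the data were examined matched the corticospinal-like nuclei to the numbers of smaller classes, left out corticospinal-like nuclei, left out the 2 corticospinal-like clusters nearly absent from the Control libraries (also in the test of the difference), removed scrublet's own calls, and named clusters by marker counts alone. Some list members past the threshold are not reported here.

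The tests were run on simulated counts with the means, sizes and spread of these libraries and 200 genes changed. In simulated corticospinal-like sums of 17265 genes, 13.4% of 1.5-fold, 31.3% of 2-fold and 83.3% of 4-fold changes were found, with 8 false among 93 calls. In all neuron-like sums of 19311 genes these were 14.9%, 41.8% and 81.8%, with 13 false among 105 calls, so the false share was above the nominal 5% in both, as it was for the difference test below. In hindbrain-like sums of 15041 genes 9%, 31.3% and 84.8% were found, and in red nucleus or midbrain-like sums of 12114 genes 4.5%, 32.8% and 84.8%. For the difference test, simulated without the spread that both sums of a library share, over 18583 genes, 74.2% of 4-fold and 1.5% of 2-fold changes were found, with 5 false among 56 calls. A simulated list raised 1.5-fold was found among 17283 genes, with 0 of 14 lists without raised members called. The simulated genes varied independently of each other. In the real corticospinal-like nuclei the estimated correlation ranged from −0.02 for regeneration-associated to 0.58 for cholesterol synthesis genes. The simulation therefore does not show how often lists whose members vary together are called falsely.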

Results

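Gene expression was measured in single nuclei of brain neurons that project to the spinal cord, in 2 libraries labelled Control and 2 labelled Sox11, taken 2 weeks after virus delivery. The deposited UMI counts held 3681 and 2352 barcodes in Control 1 and Control 2, and 2166 and 4383 in Sox11 1 and Sox11 2, with 34215523 to 61679959 UMIs per library. After filtering, 3121, 2269, 2061 and 3823 neuron-like nuclei remained in Control 1, Control 2, Sox11 1 and Sox11 2. The comparisons asked how the expression of corticospinal and other supraspinal neurons differed between the Sox11-labelled and the Control libraries.

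Corticospinal-like nuclei, named from markers such as Fezf2, Bcl11b and Crym, were the largest class in every library. Their share of neuron-like nuclei was 42.2% (exact 95% interval 40.4% to 43.9%) in Control 1, 46.0% (43.9% to 48.1%) in Control 2, 70.8% (68.8% to 72.7%) in Sox11 1 and 53.7% (52.1% to 55.3%) in Sox11 2. Hindbrain-like nuclei made up 15.0%, 30.01%, 14.5% and 17.7% of the libraries in the same order, with the Control libraries far apart. With clusters named by marker counts alone, which adds clusters 0 and 15, these shares were 34.9%, 35.6%, 16.4% and 27.1%. Red nucleus or midbrain-like nuclei made up 5.48%, 5.16%, 6.16% and 9.39%, and unnamed clusters 32.4%, 16.0%, 7.04% and 16.0%. Oligodendrocyte-like nuclei were 1.78%, 0.784%, 0.957% and 1.77% of all clustered nuclei. The fluorescence sort, the spread of the virus and the dissection can each set such shares, and no test was made of them. With the doublets that scrublet's own threshold marked removed, 938 of 1459 corticospinal-like nuclei stayed in Sox11 1 and all in the other libraries. Shares were not recomputed with that removal.

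**Figure D1:**
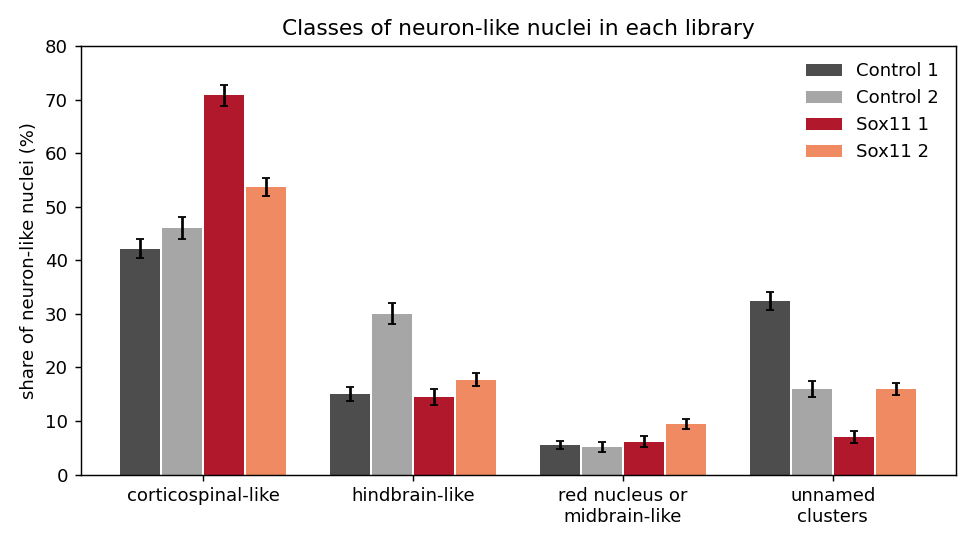
Share of neuron-like nuclei (percent, y axis) in each of 4 groups of clusters (x axis), with 1 bar per library and exact 95% binomial intervals as error bars. Corticospinal-like nuclei take 42.2% and 46.0% in the Control libraries and 70.8% and 53.7% in the Sox11-labelled libraries.

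The Sox11 gene (ENSMUSG00000063632, chromosome 12, 27334264 to 27342574, mm10) was not measurably higher in the Sox11-labelled libraries. In all neuron-like nuclei its level was 14.6 ± 1.65 CPM in the Control libraries and 11.96 ± 1.78 CPM in the Sox11-labelled libraries (SD, n = 2 each), a log2 fold change of −0.29 (SE 0.20, edgeR adjusted p = 0.544). In corticospinal-like nuclei it was 1.98 ± 0.234 and 2.68 ± 0.588 CPM, a log2 fold change of 0.43 (SE 0.34, edgeR adjusted p = 0.542). These nuclei, low in Sox11, took a larger share in the Sox11-labelled libraries, which can lower the level over all neuron-like nuclei. Over the neuron-like nuclei without them the log2 fold change was no longer negative. A 3′ tag does not need to count RNA from a vector as the Sox11 gene, so these values check nothing about the virus, and the libraries are called Sox11-labelled throughout. The gene tables of both Sox11-labelled libraries also held a separate vector entry named Sox11, with 10 UMIs in each, which the Control tables lacked. How reads shared by entry and gene were counted is not given, so the level of this gene may not compare between the groups.

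In corticospinal-like nuclei 585 of 17338 genes passed the threshold between the Sox11-labelled and the Control libraries, 413 higher and 172 lower. Gpc2, a heparan sulfate proteoglycan of developing neurons, rose by 7.12 on the log2 scale (SE 0.45, edgeR adjusted p = 0.000288), from 0.175 ± 0.0993 to 25.2 ± 8.85 CPM (SD, n = 2 each). Zfp57, a zinc finger protein that protects DNA methylation at imprinted genes, rose by 6.27 (SE 0.29, adjusted p = 6.11e-05), from 0.355 ± 0.0163 to 27.7 ± 0.697 CPM. Alcam, a cell adhesion molecule, fell by 1.48 (SE 0.17, adjusted p = 0.00283), from 130.4 ± 4.77 to 46.7 ± 6.27 CPM, and Syt2, a calcium sensor of transmitter release, fell by 1.47 (SE 0.20, adjusted p = 0.00790). Gpc2 (ENSMUSG00000029510) lies on chromosome 5 from 138273655 to 138280005, Zfp57 (ENSMUSG00000036036) on chromosome 17 from 37001163 to 37010635, Alcam (ENSMUSG00000022636) on chromosome 16 from 52248996 to 52454074 and Syt2 (ENSMUSG00000026452) on chromosome 1 from 134646677 to 134762593. The fold of Gpc2 rests on few Control molecules, 5 and 2 UMIs in the Control libraries against 1067 and 686.

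Among genes with a mean of 10 CPM or more and no overlap between the groups in corticospinal-like nuclei, Kcnk2, a background potassium channel, rose by 4.48 (SE 0.45), and Kcnmb2, a subunit of calcium-activated potassium channels, by 3.22 (SE 0.35). Chn2, which inactivates the small GTPase Rac, rose by 4.76 (SE 0.48), Thsd7a by 4.10 (SE 0.29), Soga1 by 4.00, Psd2 by 3.58 and the actin-binding gene Cald1 by 3.47. The transcription factor genes Tox3 and Etv4 rose by 3.85 (SE 0.31) and 3.61 (SE 0.74), and Vcan, a matrix proteoglycan, by 3.68 (SE 0.23). The rise of Etv4 rested on uneven levels, 31.8 CPM in Sox11 1 and 7.47 CPM in Sox11 2, and its edgeR adjusted p was 0.0357. The call of Etv4 was lost by DESeq2 (adjusted p = 0.0704) and with the marker gate (0.0588), and over its alternatives the adjusted p ranged from 8.37e-17 without Control 1 to 0.919 without corticospinal-like clusters 27 and 28. Besides Alcam and Syt2, the largest falls among such genes were of the calcium-binding gene Tesc (−1.67, SE 0.22), the phosphodiesterase gene Pde7b (−1.52), the kinase gene Prkd1 (−1.49), the vesicle gene Rab26 (−1.49) and the axon guidance receptor gene Robo3 (−1.39), with Tex22, Vwc2 (−1.48), Churc1 (−1.44), Blnk (−1.39) and Pdzrn4 among them. The edgeR adjusted p of these genes ranged from 6.11e-05 for Zfp57 to 0.0357 for Etv4. Corticospinal-like clusters 27 and 28 held almost only nuclei of the Sox11-labelled libraries. They were formed from expression, so the most changed nuclei may be left out with them, and calls lost that way do not weigh the changes. Without these clusters the 12 rises and the 12 falls all lost the threshold, with edgeR adjusted p from 0.798 to 0.997. Chn2 then stood at 0.13, Psd2 at 0.26, Vcan at 0.42, Kcnk2 at 0.48, Thsd7a at 0.49 and Soga1 at 0.65, against 3.18 for Gpc2, 2.21 for Zfp57, −0.68 for Alcam and −0.37 for Syt2. With nuclei matched in number to smaller classes, Blnk (adjusted p = 0.0535, hindbrain-like numbers) and Robo3 (0.0975), Tex22 (0.0979) and Churc1 (0.104, red nucleus or midbrain-like numbers) lost it too, and over their alternatives the adjusted p of these 4 genes ranged from 2.00e-05 for Tex22 to 0.961 for Robo3.

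**Figure D2:**
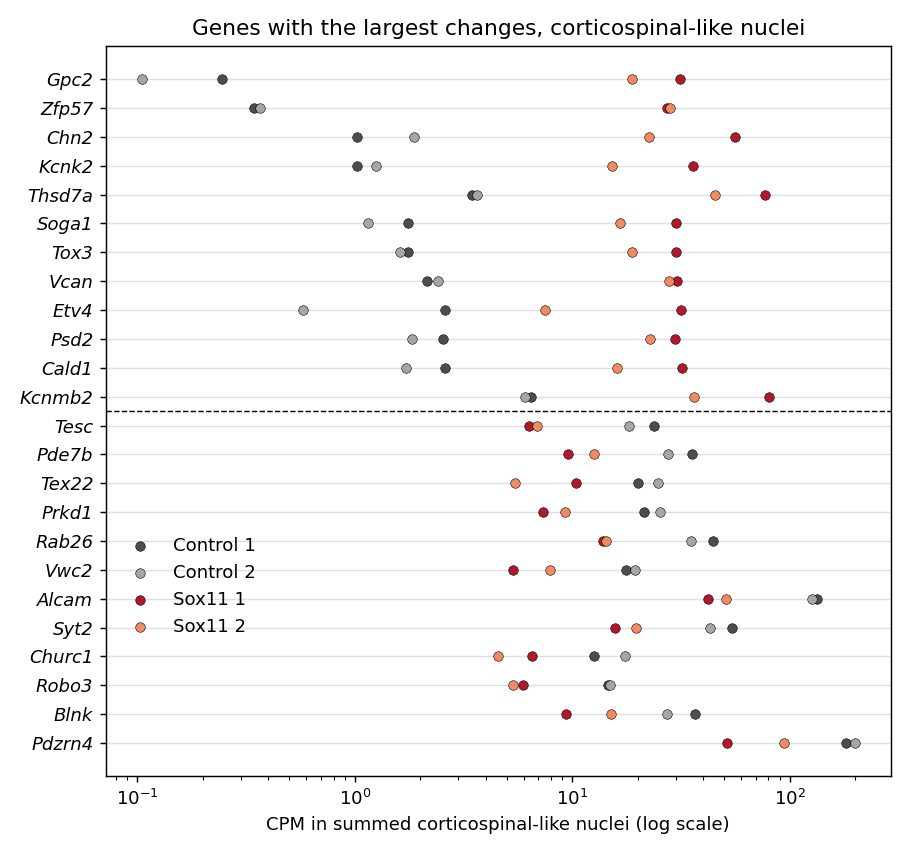
CPM in summed corticospinal-like nuclei (x axis, log scale) of the 12 genes with the largest rise (above the dashed line) and the 12 with the largest fall among those with a mean CPM of 10 or more and no overlap between the groups, 1 point per library. For Zfp57 both Sox11-labelled libraries lie at 27.2 and 28.2 CPM and both Control libraries under 0.367 CPM.

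Of the fixed lists, immature neuron genes had the lowest camera p in corticospinal-like nuclei. Of 39 measured members 8 rose, 0 fell and 31 did not pass, and 20 rose when adjusted over the list alone, with a median log2 fold change of 0.52. Dpysl3 and Dpysl5, which steer microtubules in growing axons, rose by 2.58 and 2.67, Dcx, a microtubule-binding protein of migrating neurons, by 1.78 and Mex3a by 5.09. Cytoskeleton and growth cone genes rose in 7 of 51 members and fell in 0, and 12 rose and 3 fell when adjusted over the list alone. Tubb2b, a neuronal tubulin, rose by 2.99 and Stmn1, which destabilises microtubules, by 1.45, and 6 of the 7 that rose, all but Evl (1.15), are also on the immature neuron list. By camera the adjusted p was 4.18e-17 for immature neuron genes and 3.97e-07 for cytoskeleton genes, and with an estimated correlation the adjusted p was 0.159 and 0.541.

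Axon guidance ligands and receptors rose in 7 of 63 members and fell in 1, with 9 and 3 when adjusted over the list alone. The semaphorin genes Sema6a, Sema6c, Sema3a and Sema6d rose by 2.96, 1.93, 1.44 and 1.06, and Robo3 fell by 1.39. The camera adjusted p was 0.00348, and the adjusted p with an estimated correlation was 0.675. Without Control 2 the camera adjusted p of this list was 0.261, against 4.32e-05 without Control 1. Among histone acetylation and chromatin remodelling genes 1 of 43 rose, Ezh2, a histone methyltransferase, by 1.79 (1 and 0 when adjusted over the list alone). The camera adjusted p of that list was 0.0494, its adjusted p with an estimated correlation 0.875, and by camera the adjusted p was 0.0558 with the size factors of DESeq2 and ranged from 0.00148 without Control 1 to 0.682 without Control 2.

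Cholesterol synthesis genes and nuclear-encoded genes of oxidative phosphorylation were lower as lists by camera (adjusted p = 1.04e-08 and 3.84e-09), and with an estimated correlation the adjusted p was 0.675 and 0.646. Of 22 cholesterol genes 2 fell and 0 rose, and 11 fell when adjusted over the list alone, with a median of −0.68. Srebf2, the transcription factor of the pathway, fell by 0.75, while Hmgcs1 stood at −0.85 without passing (adjusted p = 0.0612). Of 39 oxidative phosphorylation genes 0 passed, also when adjusted over the list alone, with a median of −0.50, and Uqcrc1 and Cox5b stood at −0.66 and −0.91. Genes of oxidative phosphorylation were also lower in oligodendrocyte-like nuclei, at 2627 and 2484 summed CPM in the Control and 1679 and 1737 in the Sox11-labelled libraries.

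The remaining lists were not called by camera in corticospinal-like nuclei. Of 31 regeneration-associated genes 5 rose and 1 fell (7 and 3 when adjusted over the list alone, camera adjusted p = 0.0999). The adhesion genes L1cam and Chl1 rose by 1.16 and 0.76 and the transcription factor gene Klf7 by 0.74, whereas Jun, another transcription factor gene of the list, fell by 1.91. Of 45 synaptic vesicle genes 0 rose and 5 fell (1 and 6 when adjusted over the list alone, camera adjusted p = 0.107), among them Syt2, Cplx2 (−0.83), Syn2 (−0.80) and Vamp2 (−0.80). Of 65 voltage-gated ion channel genes 3 rose and 2 fell (6 and 3 when adjusted over the list alone, camera adjusted p = 0.417). The sodium channel gene Scn3a rose by 1.44 and the calcium channel subunit gene Cacnb3 by 1.67, and the potassium channel subunit gene Kcnab3 fell by 1.84. Of 27 cadherins and protocadherins Fat4 (2.13) and Cdh2 (0.79) rose and Pcdh20 (−2.10) fell (3 and 8 when adjusted over the list alone, camera adjusted p = 0.568).

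Of 34 integrin and matrix genes Vcan and Itgb8 (3.25) rose and Hapln4 (−1.90) and Bcan (−1.59), which bind hyaluronan in the matrix, fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.639). Of 36 genes of Wnt, BMP and TGF-beta signalling the receptor gene Tgfbr1 rose by 1.66, and Bmpr1b (−1.26) and Chrd (−1.14) fell (4 and 6 when adjusted over the list alone, camera adjusted p = 0.806). That list's median was 0.07, its mean −0.03 and its camera direction down. Of 22 cell stress genes 1 rose and 2 fell, Jun and Gadd45b (−1.15) (3 and 4 when adjusted over the list alone, camera adjusted p = 0.609). Of 44 glutamate receptor and scaffold genes Grm3 rose by 0.83 (1 and 1 when adjusted over the list alone, camera adjusted p = 0.679). For 15 GABA receptor genes, 17 immediate early genes and 17 interferon genes 0 passed, also when adjusted over each list alone, with camera adjusted p of 0.938, 0.113 and 0.924. The interferon list's median was 0.39 while its camera direction was down.

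**Figure D3:**
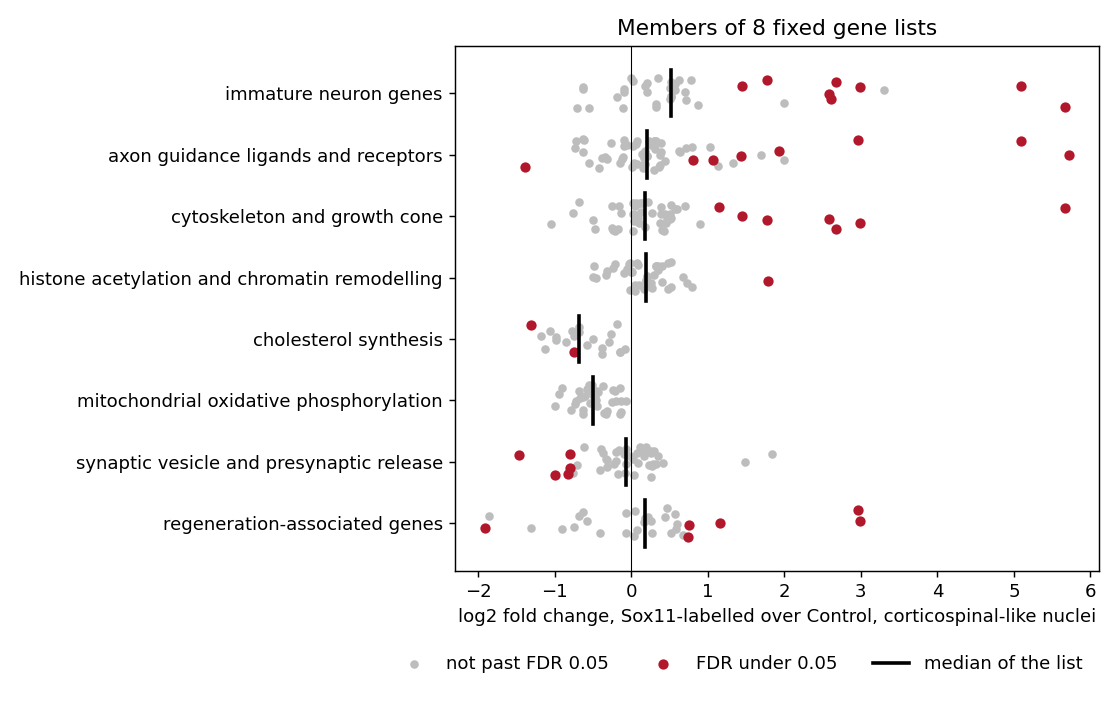
Log2 fold change, Sox11-labelled over Control, in corticospinal-like nuclei (x axis) of the members of 8 fixed lists (y axis, with random vertical scatter), red where the edgeR adjusted p was under 0.05, with the list median as a black line. The median is 0.52 for immature neuron genes and −0.68 for cholesterol synthesis.

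Among cell type markers, 0 of 15 corticospinal markers passed in corticospinal-like nuclei by edgeR (median 0.061), which checks little because the clusters were named by these markers. Of 64 testable members of 16 other cell type lists 3 were higher, Mog, Vcan and Col1a1, and 0 were lower, and for the cholinergic list 0 members could be tested. The class was held by different clusters in the groups. Corticospinal-like clusters 27 and 28 held 1, 1, 27 and 600 and 1, 0, 1102 and 701 nuclei in Control 1, Control 2, Sox11 1 and Sox11 2, and without both 1 gene passed in the remaining corticospinal-like nuclei, Shoc1 (2.31, SE 0.204, edgeR adjusted p = 0.0311), with 862 genes at an unadjusted p under 0.05. The 513 changed genes tested there had a median change of 0.37 in their direction, against 1.39 in all corticospinal-like nuclei. Both clusters were formed from expression and hold almost only nuclei of the Sox11-labelled libraries, so that count does not show where the changes lie. The count was 986 by DESeq2, 294 with nuclei matched in number to the red nucleus or midbrain-like class, 929 without Control 2 and 1561 without Sox11 2.

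Over all neuron-like nuclei, 28 of 19311 genes rose in the Sox11-labelled libraries and 0 fell by edgeR, with 2811 at an unadjusted p under 0.05. Gpc2 rose by 4.62 (SE 0.42, adjusted p = 0.0237), from 0.829 ± 0.0181 to 20.5 ± 10.5 CPM (SD, n = 2 each), Zfp57 by 2.48 (SE 0.19, adjusted p = 0.0237) and Vcan by 1.91 (SE 0.19, adjusted p = 0.0237). Shoc1, known from meiosis, rose by 2.24 (SE 0.25, adjusted p = 0.0386) and Dcx by 1.33 (SE 0.17, adjusted p = 0.0426). The growth factor receptor gene Tgfbr1 rose by 1.41, the cadherin gene Fat4 by 1.58, Ezh2 by 1.33, Lix1 by 1.34, Jpt1 by 1.35, Nckap5 by 1.39 and Tmem131l by 1.46. Shoc1 (ENSMUSG00000038598) lies on chromosome 4 from 59043753 to 59138983, Vcan (ENSMUSG00000021614) on chromosome 13 from 89655312 to 89742509 and Dcx (ENSMUSG00000031285) on chromosome X from 143855842 to 143933311. By DESeq2 the fall count was 140 and the rise count 417. These sums mix classes whose shares differed between libraries, and without corticospinal-like nuclei 0 of 17445 genes passed by edgeR (956 at an unadjusted p under 0.05), with Shoc1 at 2.10, Gpc2 at 2.01, Zfp57 at 1.03, Dcx at 0.36, Vcan at 0.13, Lix1 at −0.17 and Sox11 at 0.07. The count was 99 without Control 1, 259 without Control 2, 5 without Sox11 1 and 217 without Sox11 2.

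In all neuron-like nuclei camera called 8 lists, the 6 called in corticospinal-like nuclei and those of ion channels and glutamate receptors, with a lowest adjusted p of 0.312 with an estimated correlation. Immature neuron genes rose in 4 of 40 members (14 when adjusted over the list alone, camera adjusted p = 4.40e-13), with Mex3a at 4.54, Marcksl1, an actin-binding protein of growth cones, at 3.73 and Stmn1 at 1.17. Cytoskeleton genes rose in 3 of 51 members and fell in 0 (8 and 1 when adjusted over the list alone, camera adjusted p = 1.13e-05), and axon guidance genes rose in 1 of 64, Plxnb1 at 4.02 (5 and 1 when adjusted over the list alone, camera adjusted p = 0.00658). Ion channel genes (0.00559), glutamate receptor genes (0.00586) and chromatin genes (0.0432) were higher and oxidative phosphorylation (2.88e-11) and cholesterol genes (0.000177) lower by camera adjusted p, with 0 members passing except Ezh2. For the other 9 lists the camera adjusted p was 0.158 or more. The sums of the other neuron-like nuclei, given next, also mix classes whose shares differed between libraries. In neuron-like nuclei other than corticospinal-like, oxidative phosphorylation (3.36e-13) was lower and ion channel (0.000402), immature neuron (0.0103) and glutamate receptor genes (0.0103) higher by camera adjusted p, with 0 members passing and an adjusted p of 0.449 or more with an estimated correlation.

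In hindbrain-like nuclei 0 of 15100 genes passed by edgeR, with 719 at an unadjusted p under 0.05 and 4 genes by DESeq2, and with clusters 0 and 15 added 0 of 15987, with 715 and 2. In red nucleus or midbrain-like nuclei 0 of 12082 passed, with 447 at an unadjusted p under 0.05 and 2 by DESeq2. Among the lowest p-values, Zranb2, which encodes a splicing-related zinc finger protein, stood at −0.80 (SE 0.13, edgeR adjusted p = 0.460) in hindbrain-like and −0.87 (SE 0.13, adjusted p = 0.211) in red nucleus or midbrain-like nuclei. Sepsecs, an enzyme of selenocysteine tRNA synthesis, stood at −1.15 (adjusted p = 0.373) and −1.04 (adjusted p = 0.830). In hindbrain-like nuclei Marcksl1 stood at 2.51 and Zfp57 at 1.17 (adjusted p = 0.997 for both), with 11.5 ± 1.82 and 26.2 ± 5.70 CPM of Zfp57 (SD, n = 2 each). In red nucleus or midbrain-like nuclei Shoc1 stood at 1.79 (adjusted p = 0.634), Fnbp1l at 1.68 and Churc1 at −1.76 (adjusted p = 0.843 for both). In unnamed clusters 0, 1 and 2 edgeR passed 0 of 12584, 10821 and 6905 genes, with 608, 695 and 447 at an unadjusted p under 0.05, and DESeq2 passed 0, 1 and 0. Zranb2 stood at −0.73 in cluster 0 and −0.80 in cluster 1, and Zfp57 at 1.67 in cluster 1 (adjusted p = 0.131). In cluster 2 the glycolytic genes Gapdh and Pkm stood at −1.54 and −1.73 (adjusted p = 0.290 and 0.294). Over these 5 classes together, leaving out Control 1, Control 2, Sox11 1 or Sox11 2 gave 172, 172, 106 and 266 genes, with the lone library assumed to vary like the other group.

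The change differed between corticospinal-like and the other neuron-like nuclei for 905 of 18664 genes in the test of the difference itself, 520 with a higher and 385 with a lower log2 fold change in corticospinal-like nuclei. The other sums mixed classes whose shares differed between libraries. Midbrain-like nuclei were 171 of 1805 of them in Control 1, 117 of 1225 in Control 2, 127 of 602 in Sox11 1 and 359 of 1771 in Sox11 2. Part of the differences may come from that mix, which was not tested. For Zfp57 the difference was 5.24 (SE 0.25, edgeR adjusted p = 1.64e-05), from 6.27 in corticospinal-like and 1.03 in the other nuclei. Cacng4 differed by 5.14 (SE 0.33, adjusted p = 4.11e-05), Kcnk2 by 4.19 (SE 0.28, adjusted p = 4.11e-05) and Chn2 by 4.19 (SE 0.46, adjusted p = 0.000778). Syt2 stood at −1.47 in corticospinal-like and 0.40 in the other nuclei, a difference of −1.86 (SE 0.17, adjusted p = 0.000217). In the same test 14 of 40 immature neuron genes and 12 of 51 cytoskeleton genes had a higher log2 fold change in corticospinal-like than in the other nuclei, 0 and 2 a lower one (15 and 0, and 22 and 2, when adjusted over each list alone, camera adjusted p = 2.74e-12 and 1.17e-08). With an estimated correlation the adjusted p was 0.116 and 0.261. Of 22 cholesterol synthesis genes 13 differed, all lower in corticospinal-like nuclei (16 when adjusted over the list alone, camera adjusted p = 6.27e-19, and adjusted p = 0.116 with an estimated correlation). By fry the adjusted p for the difference was 0.0279 for each of the immature neuron, cytoskeleton and cholesterol lists. For all other lists the fry adjusted p was 0.143 or more. The camera adjusted p was also under 0.05 for chromatin genes (0.00686, higher), synaptic vesicle genes (0.00686, lower), cadherins (0.0106, lower) and oxidative phosphorylation (0.0154, lower), each with an adjusted p of 0.598 with an estimated correlation. The count of genes was 437 without Control 1, 421 without Control 2 and 471 without Sox11 1. Without corticospinal-like clusters 27 and 28 it was 0 of 18158 by edgeR, with 850 at an unadjusted p under 0.05 against 3472 with them, and Chn2 stood at −0.28 and Zfp57 at 1.19. These clusters, formed from expression, hold almost only nuclei of the Sox11-labelled libraries. The difference was therefore not shown for the corticospinal-like nuclei that both groups held. Leaving out the most changed nuclei may itself bring the count down.

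**Figure D4:**
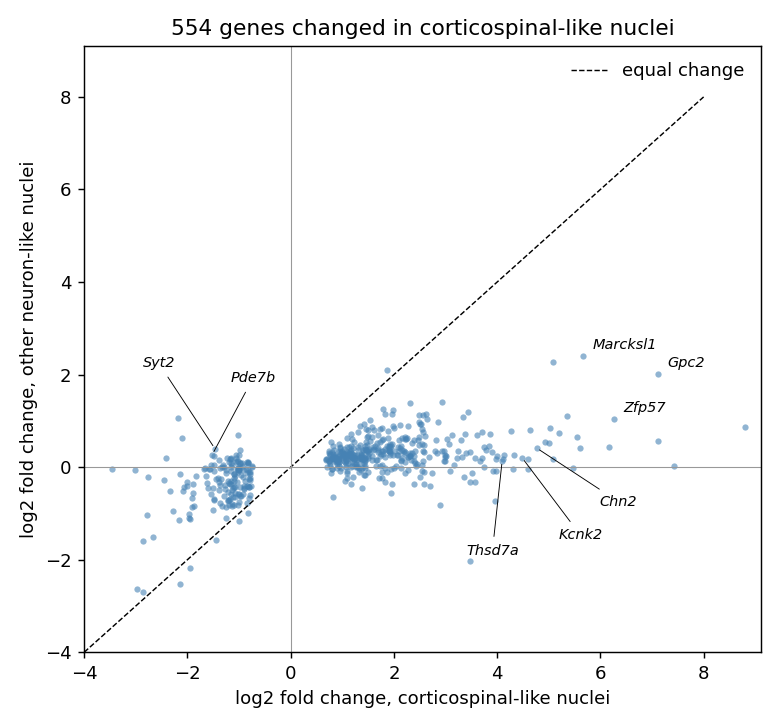
Log2 fold change, Sox11-labelled over Control, of 554 genes changed in corticospinal-like nuclei, in those nuclei (x axis) and in the other neuron-like nuclei (y axis), 1 point per gene. The dashed line marks equal change, and the median change in each gene's corticospinal direction is 1.45 on the x axis and 0.27 on the y axis.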

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

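The test of the difference between corticospinal-like and other neuron-like nuclei was planned, and the tests that weigh explanations in the paragraphs that follow were chosen after the results were seen, as were the difference test without clusters 27 and 28 and the use of the planned count to weigh a difference that all nuclei share, with bounds set when that count was known.

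The effect differed between corticospinal-like and other neuron-like nuclei for 905 genes, by a test of the difference itself. The differences, corticospinal-like minus other, were 5.24 for Zfp57, 5.14 for Cacng4, 4.19 for Kcnk2, 4.19 for Chn2, 3.92 for Thsd7a and 3.77 for Nox4, an oxidase gene. They were −2.26 for Dnase1l3, −2.23 for Tll1, −1.86 for Syt2, −1.79 for Pde7b, −1.75 for Colgalt2 and −1.74 for Bves. Dnase1l3 stood at −1.36 in corticospinal-like and 0.93 in the other nuclei, and Tll1 at −1.57 and 0.64. For Nox4 the edgeR adjusted p was 0.0882 without Control 1 and 0.119 without Control 2, for Dnase1l3 0.0653 without Control 2 and 0.175 without Sox11 1, and for Bves 0.149 without Sox11 2, in a range over their alternatives from 3.83e-21 to 0.9995, both for Nox4. The count was 437 without Control 1, 421 without Control 2 and 471 without Sox11 1. Without corticospinal-like clusters 27 and 28, almost absent from the Control libraries, it was 0 by edgeR (850 at an unadjusted p under 0.05), and Chn2 (−0.28) and Nox4 (−0.51) stood below 0.

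For the larger changes in corticospinal-like nuclei, 905 of all genes tested had an effect that differed. That count argues against a difference that scales each gene alike in all nuclei of a library as the whole cause. The mix of classes in the other neuron-like sums differed between libraries and may add to the 905 genes. The test of the difference does not weigh a shared difference that adds to the counts, because log2 fold changes then differ wherever Control levels differ. Zfp57 stood at 0.355 CPM in corticospinal-like and 11.5 CPM in hindbrain-like nuclei of the Control libraries. In the Sox11-labelled libraries it stood at 27.7 and 26.2 CPM. Summed over 359 genes raised in corticospinal-like nuclei, the rise in CPM in hindbrain-like nuclei was 21.6% of that in corticospinal-like nuclei. For these genes this argues against an equal addition in all nuclei as the whole cause. The genes were chosen in corticospinal-like nuclei, which favours a larger rise there. Both arguments hold for sums with clusters 27 and 28. Without them 0 genes differed by edgeR (850 at an unadjusted p under 0.05). The changed genes then had a median change in their direction of 0.37, against 1.39 in all corticospinal-like nuclei (513 genes). For the other corticospinal-like nuclei larger changes were therefore not shown and a shared difference is not excluded. As the clusters were formed from expression, the small change may also follow from leaving out the most changed nuclei, so it decides nothing. For nuclei of the cell types on the other marker lists, 0 of 16 lists had as many testable members higher by edgeR as not (3 of 64 members in all). This decides little, because clusters were named corticospinal-like only where no other list had as many raised markers. Some lists also had few testable members, such as 1 serotonergic and 2 hindbrain markers. Astrocyte markers summed to 199 and 158 CPM in the Control and 287 and 240 CPM in the Sox11-labelled libraries. Of the 7 astrocyte markers tested 0 passed by edgeR, with a median log2 fold change of −0.008, so the list did not rise together. Because of the naming and the few testable members, nuclei of these types are not excluded. Too few nuclei elsewhere are argued against by the 294 genes called after matching to the number of red nucleus or midbrain-like nuclei. A cell type on none of the lists and a different mix of corticospinal-like nuclei in the libraries stay open, as does a difference between the preparations of the groups that acts on corticospinal-like nuclei alone, which the labels do not separate from the groups. Cell Ranger version and reference apply to all nuclei of a library. A response of these neurons to the Sox11 virus also stays open.

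For the lower oxidative phosphorylation genes, a difference shared by all nuclei of a library may be a cause. Their summed CPM was lower in oligodendrocyte-like nuclei too, by a log2 ratio of −0.58. Ribosomal protein genes had a median of −0.25 in corticospinal-like (bootstrap 95% interval −0.31 to −0.20) and −0.42 in the other neuron-like nuclei. Less cytoplasmic RNA carried over with the nuclei would give such values. The interval resamples genes with the libraries held fixed and leaves out the spread between libraries. The nuclear RNA Malat1 did not pass in either (−0.77, SE 0.26, edgeR adjusted p = 0.146, and −0.06, SE 0.11, adjusted p = 0.975), although less cytoplasmic RNA would raise it. A lower expression in the neurons themselves stays open.

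The genes raised in corticospinal-like nuclei stood slightly higher in hindbrain-like nuclei, with a median of 0.25 (bootstrap 95% interval 0.21 to 0.28, 84.1% of 359 genes above 0). The summed rise was 3.65 times (2.81 to 4.52) that predicted from 7 forebrain markers. In these 4 libraries this argues against free RNA from corticospinal nuclei alone. Both intervals resample genes with the libraries held fixed, so they leave out the spread between libraries. The prediction used the markers' CPM in hindbrain-like nuclei as a share of that in corticospinal-like nuclei. This share was 5.21% and 2.76% in Control 1 and Control 2 and 5.21% and 4.96% in Sox11 1 and Sox11 2. A library difference shared by all nuclei and a response of the hindbrain neurons cannot be told apart by that median of 0.25, because each would raise these genes and version and reference followed the groups.

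Vector entries of the gene tables, outside the main measurement, held UMIs in 3 libraries, and as the tables of the groups held different entries most counts have no Control value. In Sox11 2 the entry BC102 held 30596 UMIs, mGL 296, BC0 186, BC1 32 and Sox11 10. In Sox11 1 mGL held 163, BC1 69, BC0 19 and Sox11 10. In Control 2 CAGIG-ddDLK held 59 and New-H2B-mGL 39. The labels used here do not say what these entries are.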

How the results depend on the processing

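The tests with matched nuclei, without corticospinal-like nuclei, without clusters 27 and 28, with scrublet's own calls removed and with clusters named by marker counts alone were chosen after the results were seen. Of 90 alternative values of counts and main values 60 stayed the same, 29 moved and 1 reversed, of 48 class shares 42 stayed and 6 moved, and of 1330 for single genes, lists and classes 1029 stayed, 170 crossed to past the threshold, 97 lost it, 31 moved and 3 reversed. In all neuron-like nuclei the 28 genes became 44 with the size factors of DESeq2, 915 without a filter, 557 by DESeq2, 54 with 2000 detected genes and 5 to 259 without 1 library. Without corticospinal-like nuclei edgeR passed 0 (956 at an unadjusted p under 0.05), Lix1 reversed to −0.17 (adjusted p = 0.962) and Sox11 to 0.0675 (SE 0.174, adjusted p = 0.984). In corticospinal-like nuclei the 585 became 986 by DESeq2 (558 shared), 294 with nuclei matched to the midbrain-like class (254 shared), 1 without clusters 27 and 28, and 511 to 1561 without 1 library. The other alternatives gave 424 to 754, and resolutions 0.5 and 2 gave the same sums. In the other classes the 0 (edgeR) became 269 without a filter, 7 by DESeq2 and 106 to 266 without 1 library. The 905 of the difference became 1911 without a filter and 421 to 729 without 1 library, and without clusters 27 and 28 edgeR passed 0 (850 at an unadjusted p under 0.05), with Chn2 reversed to −0.28 and Nox4 to −0.51 (adjusted p = 0.9995 for both). Of 6 lists called by camera in corticospinal-like nuclei 0 were called with an estimated correlation and 0 by fry (lowest adjusted p = 0.159 and 0.0574). At resolution 2 the hindbrain-like share was 18.4% in Control 1 and 32.5% in Control 2, and with clusters named by marker counts alone 34.9%, 35.6%, 16.4% and 27.1% in Control 1, Control 2, Sox11 1 and Sox11 2. For these moves the cause was not tested.

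The libraries of the groups share only replicate numbers, and deviations from the group means of libraries with the same number correlated at 0.0194 in corticospinal-like and −0.0237 in all neuron-like sums, so no pairing was used. With the number as a block, edgeR passed 0 genes in all neuron-like nuclei (2910 at an unadjusted p under 0.05), where Gpc2 stood at 4.54 and Vcan at 1.91 (adjusted p = 0.0941 for both) and Dcx at 1.33 (adjusted p = 0.147), 751 in corticospinal-like nuclei (571 shared) and 211 in the other classes, and the camera adjusted p of chromatin genes was 0.0567.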

Other observations

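The tests in this part were chosen after the results were seen, except the prediction for hindbrain-like and midbrain-like nuclei, which was written before its values. That such a bound was out of reach there was worked out after them.

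In Sox11 2, UMIs of the vector entry BC102 were spread unevenly over the neuron classes. Corticospinal-like clusters 27 and 28 held 13.9 and 7.56 BC102 UMIs per 10000 UMIs and the other corticospinal-like nuclei 2.09. Midbrain-like nuclei held 4.71, hindbrain-like 2.84, oligodendrocyte-like 1.65 and inhibitory nuclei 0.264. UMIs of BC102 were found in 2611 barcodes, 59.6% of that library. The gene table of Sox11 1 held the entry too, with 0 UMIs. The share of UMIs from the 954 response genes used below was 4.56% in its corticospinal-like nuclei. It was 3.38% in Sox11 2 and 1.90% and 1.99% in the Control libraries. These genes were chosen as raised in Sox11 1 against the Control libraries. Their high share in Sox11 1 follows from that choice and says nothing about BC102.

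A candidate explanation for stronger changes in some nuclei of Sox11 2 was a higher level of that entry. The share of UMIs from 954 genes raised without Sox11 2 was compared after thinning each nucleus to 4000 UMIs, which left out 162 and 208 shallower nuclei of the classes compared. In corticospinal-like nuclei it was 2.94% with 0, 3.52% with 1 or 2 and 3.91% with 3 or more BC102 UMIs, a ratio of 1.33, between the bounds of 1.1 and 1.5, which for this class were set after the values were seen, and so undecided. Within clusters 27 and 28 the ratio was 1.06 (4.04%, 4.17% and 4.28%) and in the other corticospinal-like nuclei 0.983 (2.06%, 2.05% and 2.03%), so most of the 1.33 went with the mix of clusters in these bins. As the clusters were formed from expression, this split does not decide it either. In hindbrain-like and midbrain-like nuclei together it was 3.72%, 3.66% and 3.33%, a ratio of 0.897. As the mix of both differed between these bins, each was also taken alone, with 3.91%, 3.91% and 3.77% in hindbrain-like and 3.37%, 3.20% and 2.80% in midbrain-like nuclei. Neither rose with BC102, but this decides nothing. The genes were chosen in corticospinal-like nuclei, and their share in Sox11 2 was at most 1.09 times the Control mean in these classes, which can give a ratio of 1.47 at most, under the bound of 1.5. No background of BC102 was subtracted, and oligodendrocyte-like nuclei held it too.

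Other values came from the same libraries. Xist stood at 811, 0.054, 763 and 451 CPM and Ddx3y at 0, 30.2, 8.62 and 12.2 CPM in corticospinal-like nuclei of Control 1, Control 2, Sox11 1 and Sox11 2. The sex transcripts thus differed by library, of female type in Control 1, of male type in Control 2 and of both in the Sox11-labelled libraries, so the spread between the Control libraries includes that between animals of different sex. Noradrenergic-like nuclei made up 1.96%, 0.926%, 0.291% and 0.628% of neuron-like nuclei in the same order, serotonergic-like 1.47%, 0.176%, 0.097% and 0.131%, and Edinger-Westphal-like 0.224%, 1.41%, 0.388% and 1.62%.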
